A study of Oncorhynchus mykiss with 64 samples.

How the data were processed

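RNA from whole rainbow trout alevins was measured on 64 single-colour Agilent arrays, 1 array per sample, in 8 groups of 8. Per the labels' protocols, total RNA was extracted with TRIZOL, amplified and converted to Cy3 cRNA with a low-input kit, with Agilent spike-in RNA in each reaction. Each deposited scanner table gives spot intensity, per the file headers, as the mean brightness, the local background and a processed signal that Agilent Feature Extraction had background-subtracted and spatially detrended. The file headers name Feature Extraction 10.7.3.1, and the submitters' processing notes name 10.7.1.1. The processed signals had not been scaled between arrays. The deposited value table holds log2 values that differed from log2 of the processed signal by a constant on each array. Its column medians were 6.86 for the arrays before feeding and 7.12 for the fed arrays, so the time points had been centred separately there. Why the 2 centres differ is not given in the sources used here.

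From the scanner tables, log2 of the processed signal was taken and each array's 75th percentile over non-control probes was subtracted. Control spots and spots with an outlier mark were left out, and the spots of a probe were averaged. Each array held 62976 spots, of which 61657 were not controls, for 60195 probes, 1462 of them with 2 spots. A probe was kept if it was well above background on at least 6 of the 8 arrays of at least 1 group, which left 47172 probes. Of these, 39684 had a value on all arrays, and 0.328% of the kept values were missing. No spot was saturated. The number of arrays limits the precision.

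Differences were estimated with limma 3.58.1 in R 4.3.3. All 64 arrays entered a single fit with a mean per group, moderated variances with a trend, and no block. Probes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison (2-sided) were counted by direction. Counts marked unadjusted are of probes with an unadjusted p under 0.05. Without any difference, a share of 0.05 of the probes tested would be counted so on average. An unadjusted count near or below that share therefore shows no difference. Errors of log2 differences are standard errors of that fit. The labels do not say whether a sample was a single fish or a pool, nor which samples shared a tank, so p-values measure the spread between these samples, which may be technical in part. A probe that was not well above background on any array of a side, or of 1 of its groups before feeding (glucokinase), has only a bound there. Its fold was computed from the bright side's mean against the mean, per array of the dim side, of the higher of the probe's own signal and the lowest signal among probes well above background.

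Names came from the array's own name column. It holds tentative consensus numbers for 31294 probes and a gene or product name for few. Of the accessions in the tables, 4 matched the RefSeq table of assembly USDA_OmykA_1.1, and 3 of those have a symbol there. In all, 61 probes had a name, and 57 of them were kept. Several names break off after a word (fatty, delta, carnitine, lipoprotein, LDL, phosphoenolpyruvate, ATP-citrate, Slow), GR is an abbreviation with more than 1 meaning, and elov12 looks misspelt, so their products are not settled. GR was put with the antioxidant probes. Scleraxis and slow each name a pair of probes, of which the second is called so here. Genes to name were chosen by a rule: for the comparisons tested with gene lists, the 8 largest rises and 8 largest falls with adjusted p under 0.05, the 3 members of each list with the smallest p, and the brightest member that did not pass. For the other comparisons, the 3 largest in each direction were taken. Unnamed probes are given by identifier, at most 2 per direction.

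Gene lists were fixed before the data were examined, as were the groups, the tests, the naming rule and the first set of alternatives. Of 31 lists, 6 had a measured member and 2 had at least 3, which were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. These were stress and antioxidant (5 genes) and myogenesis and growth axis (3 genes). Members were matched by name, and none of the tissue marker lists had a match, so a change in a tissue's share of the body was not tested. Probes named fast mlc1, fast mlc3 and Fast myosin were measured but not matched to a list. The remaining named probes were put into groups by name after the tables had been seen, and those groups are no independent evidence. For camera alone, a missing value took the mean of its group.

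The 64 arrays lay on 8 slides, each with 1 array of every group, and were scanned on 2 days with 4 slides each. Results were recomputed with slide as a block and within each scan day. Within a single slide, which holds 1 array per group, diet and broodstock were taken as additive among the fed arrays, over the probes complete there, which left 2 residual degrees of freedom. With a mean per group nothing is left there, so the differences within a broodstock or a diet and the interaction were not tested within slides. The alternatives were normexp background correction with an offset of 50, quantile and array-median scaling, no filter and a stricter filter (8 of 8 arrays), array weights, slide as a fixed or random block, a replicate block, the deposited log2 values, and a fit of the compared groups alone. Leaving out VEG_V replicate 3, alone and with other settings, and the fits within scan days and slides were added after the data had been seen. The fit was tested on simulated values with the real spread and 200 changed probes among 39684. These values varied independently between probes and arrays, without slides or scan days, so recovery and false calls may differ in the real arrays. For diet V against M the fit recovered 44% of changes of 0.5 and 84% of changes of 1 on the log2 scale, with 5 false calls. For the broodstocks before feeding these were 18% and 68% (28% and 77% without VEG_V replicate 3), and for fed alevins against those before feeding 56% and 92%. Tables and plots used python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.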

Results

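Rainbow trout (Oncorhynchus mykiss) broodstock had received a commercial diet (COM) or a diet made wholly of plant ingredients, without fish meal and fish oil (VEG). Their alevins, the young fish around the end of yolk use, were sampled whole. Samples were taken before first feeding (COM_before and VEG_before) and after 3 weeks on diet M (fish meal and fish oil), diet C (a mixture resembling a commercial feed) or diet V (plant ingredients alone). This gave 8 groups of 8 arrays, 16 arrays before feeding and 48 after. The study asked whether the parents' diet alters how the progeny respond to first-feeding diets.

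On 63 arrays the median processed signal lay between 80.6 and 211, and 68.4% to 91.1% of probes were well above background. VEG_V replicate 3 stood apart, with a median of 1020.5, 99.96% of probes well above background and a spike-in slope of 0.891, against 1.01 to 1.08 on the others. Its mean correlation with the other arrays was 0.759, against 0.953 to 0.970. Values without this array are given beside those it moved most.

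**Figure D1:**
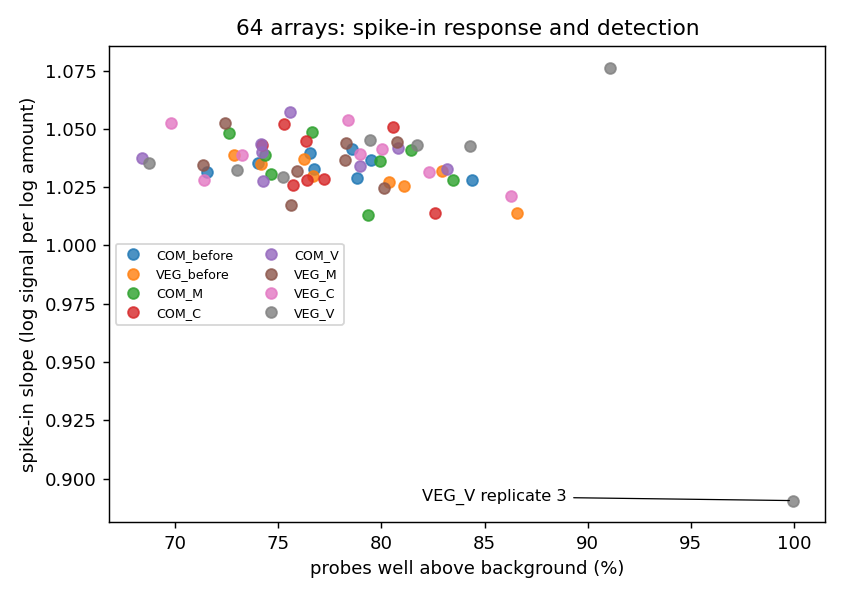
Slope of log signal on log spike-in amount (vertical axis) against the percentage of probes well above background (horizontal axis), a point per array, coloured by group. VEG_V replicate 3 sits alone at a slope of 0.891 and 99.96%.

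Several lipid and antioxidant probes were brighter in fed alevins than before first feeding. The fed alevins were also older by the 3 weeks of feeding and no unfed alevins of that age were sampled, so feeding cannot be told apart from age, development and yolk use in this comparison. The probe for elovl5b, an elongase of polyunsaturated fatty acids, was well above background on 38 of 48 fed arrays and 0 of 16 arrays before feeding. It was at least 6.66-fold higher in fed alevins (adjusted p = 3.46e-18) and lay above the mean before feeding on 48 of 48 fed arrays. The probe named elov12 rose by 2.10 ± 0.13 (log2, SE; adjusted p = 5.33e-21), a 4.29-fold rise, and that named delta by 2.22 ± 0.13 (adjusted p = 7.01e-22), each above the mean before feeding on 48 of 48 fed arrays. GPX1, which reduces peroxides with glutathione, rose by 1.44 ± 0.14 (adjusted p = 2.04e-13), from 1.96 ± 0.49 (SD, n = 16) to 3.40 ± 0.51 (n = 48), and was higher on 48 of 48 fed arrays. Glucokinase, which phosphorylates glucose in the liver, was well above background on 24 of 48 fed arrays and 1 of 16 before feeding, and was at least 3.64-fold higher in fed alevins (adjusted p = 2.59e-07).

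Other named probes were lower in fed alevins than before feeding. Glucose-6-phosphatase, which releases free glucose in the liver, fell by 1.41 ± 0.19 on the log2 scale (2.66-fold, adjusted p = 1.39e-08) and lay below the mean before feeding on 48 of 48 fed arrays. The probe named fbx32 fell by 1.75 ± 0.21 (3.37-fold, adjusted p = 7.59e-10). Carnitine, as the file names it, fell by 1.17 ± 0.13 (adjusted p = 2.21e-11) and Slow by 0.71 ± 0.08 (adjusted p = 9.26e-11), each on 48 of 48 fed arrays. The second slow probe moved less, from 5.16 ± 0.17 (SD, n = 16) to 4.93 ± 0.38 (n = 48). It lay below its mean before feeding on 41 of 48 fed arrays. Cathepsine, a lysosomal protease, fell by 0.51 ± 0.08 (adjusted p = 8.31e-07), and LC3B, a protein of autophagosome membranes, fell by 0.75 ± 0.26 (adjusted p = 0.0174). L-3-hydroxyacyl-CoA fell by 0.47 ± 0.09 (adjusted p = 2.14e-05) and MSS1 by 0.35 ± 0.09 (adjusted p = 0.00162). With the deposited values, which were centred separately per time point, the falls of cathepsine, LC3B, L-3-hydroxyacyl-CoA and MSS1 did not pass.

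The lipid and antioxidant groups below were formed after the tables had been seen. By group, 5 of 10 measured lipid probes rose and 2 fell, and the group was higher in fed alevins (camera adjusted p = 0.00221, and adjusted p = 0.0323 with an estimated correlation). Among these, fatty rose by 1.17 ± 0.11 (adjusted p = 5.24e-13). Of 8 antioxidant probes, 6 rose (camera adjusted p = 0.000253 for the group, and adjusted p = 0.0743 with an estimated correlation), among them GST, glutathione S-transferase, by 0.89 ± 0.11 (adjusted p = 2.52e-10) and the probe named GR, whose product is not settled, by 0.74 ± 0.11 (adjusted p = 8.14e-08). The 7 antioxidant probes other than GR had a mean log2 of 0.51 (camera unadjusted p = 0.000289, and unadjusted p = 0.0518 with an estimated correlation), and without VEG_V replicate 3 a mean of 0.54 (unadjusted p = 5.32e-05 and 0.00578). The stress and antioxidant list shares SOD1, SOD2, Catalase and GPX1 with the antioxidant group, so the results are not separate. In the list, SOD1, the cytosolic superoxide dismutase, rose by 0.34 ± 0.09 (adjusted p = 0.00242) and Catalase by 0.31 ± 0.10 (adjusted p = 0.00882). Both missed the threshold with array-median scaling, at adjusted p = 0.0552 and 0.0805. SOD2 differed by 0.10 ± 0.08 (adjusted p = 0.371), but by 0.13 ± 0.05 without VEG_V replicate 3, which passed (adjusted p = 0.0175), and cyp1a3 by -0.14 ± 0.12 (adjusted p = 0.363). The list as a whole was higher (mean log2 0.41, adjusted p = 0.0364), with an adjusted p = 0.234 with an estimated correlation. At the preset correlation its adjusted p was 0.0446 with slide as a block, 0.187 within scan day 1 (0.0632 without VEG_V replicate 3) and 0.0188 within scan day 2. Its mean lay above 0 on 8 of 8 slides (0.22 to 0.66).

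Of the myogenesis list, myod1, a transcription factor of muscle formation, rose by 0.48 ± 0.10 (adjusted p = 9.04e-05), while myf5 fell by 0.21 ± 0.07 (adjusted p = 0.0144), with a difference of 0.02 (adjusted p = 0.921) in the deposited values. Pax7, well above background on 29 of 48 fed arrays and 15 of 16 before feeding, differed by -0.51 ± 0.23 (adjusted p = 0.0724), but by -0.58 ± 0.21 without VEG_V replicate 3, which passed (adjusted p = 0.0208). The list, in which only these genes were matched by name, did not pass (adjusted p = 0.997), with a mean below 0 (-0.08) and a test direction above it. The probes named myogenine and mrf4 were measured but not matched to it. Their mean log2 signals went from -1.54 before feeding to -1.15 in fed alevins and from -1.93 to -2.29. Of 16 muscle and connective tissue probes 2 rose and 6 fell (2 and 10 without VEG_V replicate 3), of 10 proteolysis probes 4 fell, and of 5 nuclear receptor probes 0 passed. Among the muscle probes, mean log2 signal went from 8.36 before feeding to 8.05 in fed alevins for fast mlc1. It went from 8.49 to 8.32 for fast mlc3 and from 8.76 to 8.46 for Fast myosin. Whether the share of muscle in the body changed was not tested. PSMA1, a proteasome subunit, differed by -0.15 ± 0.10 (adjusted p = 0.232) and PPARa by 0.02 ± 0.16 (adjusted p = 0.951), or -0.06 ± 0.10 without that array (adjusted p = 0.637). In all, 14 of 57 named probes rose and 14 fell over all probes tested, and 14 and 15 adjusted over the list alone. Those counts were 16 and 18, and 16 and 19 over the list alone, without that array.

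**Figure D2:**
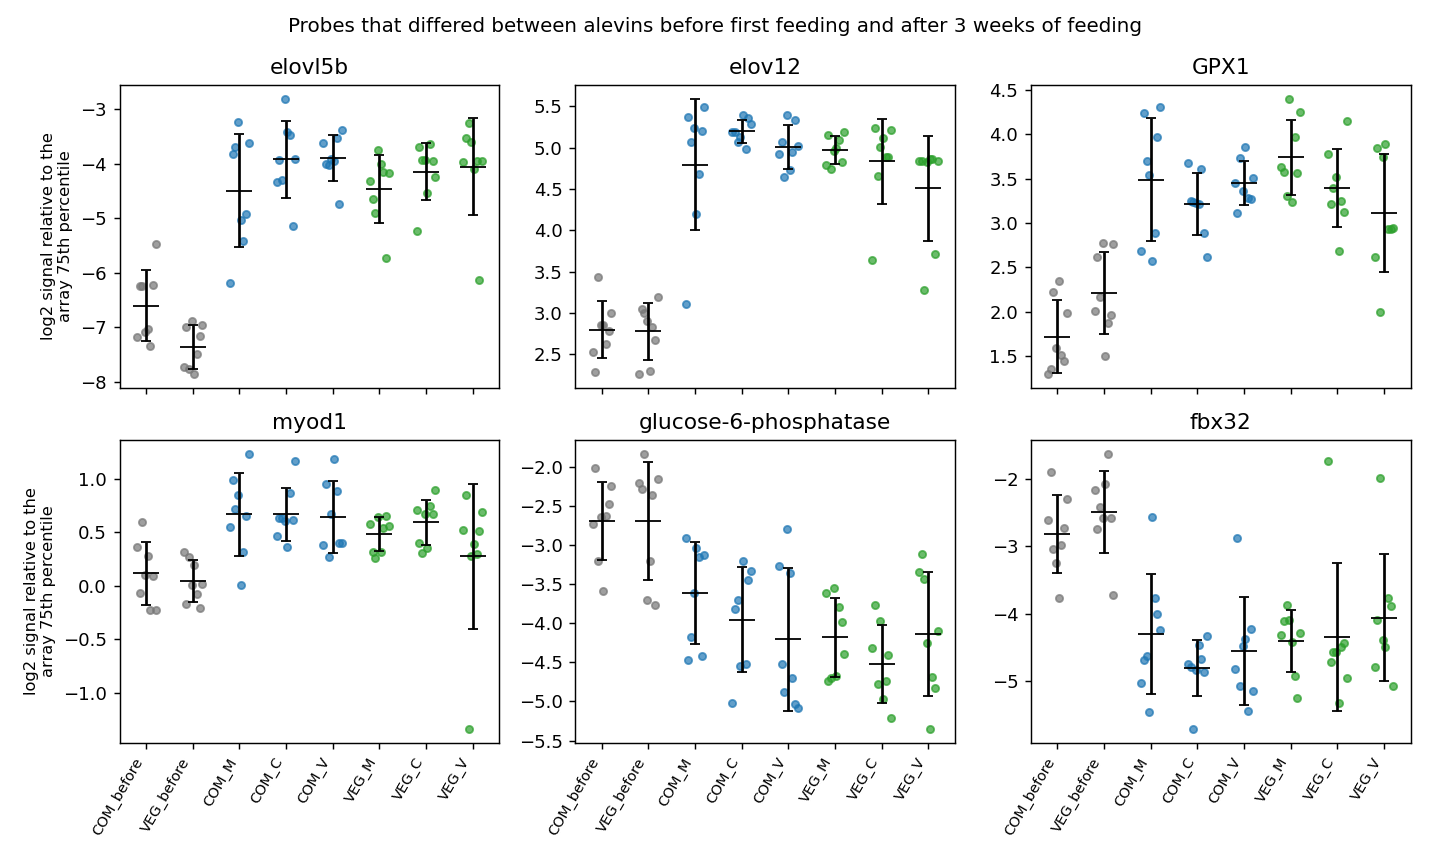
Log2 signal relative to the array 75th percentile (vertical axis) of 6 named probes in the 8 groups (horizontal axis), a point per array with the mean and SD as bars. GPX1 goes from 1.96 before feeding to 3.40 in fed alevins, and glucose-6-phosphatase lies below its mean before feeding on 48 of 48 fed arrays.

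Over all probes, 18689 of 47172 differed between fed alevins and those before feeding, 8279 higher and 10410 lower, with median log2 differences of 0.45 and -0.42. The unnamed probe TC98662 was at least 117-fold higher, seen on 47 of 48 fed arrays and 0 of 16 before, and TC115668 fell by 4.48 ± 0.34 on the log2 scale (adjusted p = 8.08e-17). The count was 20823 with slide as a block, 8608 within scan day 1 (13949 without VEG_V replicate 3) and 20036 within scan day 2. Within a single slide it was 1 to 3804, the 1 on the slide of VEG_V replicate 3 (118 without that array). The deposited values gave 16016 higher and 3001 lower, with the median of all probes at 0.18 there against -0.05 here.

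Diet V was compared with diet M in both broodstocks together, 16 arrays each. The stress and antioxidant list was lower on diet V (mean log2 -0.33, camera adjusted p = 0.000398, and adjusted p = 0.0302 with an estimated correlation). Catalase, which breaks down hydrogen peroxide, differed by -0.40 ± 0.12 (adjusted p = 0.0632) and was below the diet M mean of its broodstock on 13 of 16 arrays. SOD1 differed by -0.37 ± 0.11 (adjusted p = 0.0657) and cyp1a3 by -0.37 ± 0.14 (adjusted p = 0.177), each on 14 of 16 arrays. No member passed alone with all arrays and no block. With slide as a block Catalase (adjusted p = 0.0383) and SOD1 (adjusted p = 0.0457) fell, but not when VEG_V replicate 3 was left out as well (adjusted p = 0.0751 and 0.0859). GPX1 differed by -0.33 ± 0.17 (adjusted p = 0.310) and SOD2 by -0.16 ± 0.10 (adjusted p = 0.424), or -0.05 ± 0.06 without VEG_V replicate 3 (adjusted p = 0.855). With VEG_V replicate 3 left out the list mean was -0.24 (adjusted p = 0.00153), at -0.22 within scan day 1 (adjusted p = 0.00338) and -0.26 within scan day 2 (adjusted p = 0.0370). These p-values, and the next with slide as a block, were computed at the preset correlation alone. With slide as a block its adjusted p was 0.000834, and within single slides its mean lay below 0 on 7 of 8 (-1.04 to 0.07, the lowest on the slide of that array, at -0.32 without it). The wider group of 8 antioxidant probes, formed after the tables had been seen, had a mean log2 of -0.22 (adjusted p = 0.00759), with an adjusted p = 0.283 with an estimated correlation and 0.0654 without that array. The 7 other than GR had a mean of -0.26 (unadjusted p = 0.000556, and unadjusted p = 0.0636 with an estimated correlation), and without that array -0.16 (unadjusted p = 0.00473 and 0.0496).

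Of the 57 named probes, limma called 0 between diets V and M over all probes (17 unadjusted, 13 without VEG_V replicate 3). Adjusted over the list alone, 5 fell: Catalase, SOD1, L-3-hydroxyacyl-CoA, phosphoenolpyruvate and calpain 2, a calcium-dependent protease. The last 3 fall outside the naming rule and were chosen after their values were seen, and without VEG_V replicate 3 the count was 0. With slide as a block 4 of the named probes fell over all probes tested: Catalase, SOD1, L-3-hydroxyacyl-CoA and phosphoenolpyruvate. In that fit without that array the last 2 fell and LDL rose by 0.35 ± 0.09 (adjusted p = 0.0156). Over the list alone 1 rose and 5 fell with slide as a block, and 1 and 6 without that array as well. The myogenesis list did not pass (adjusted p = 0.408), with myod1 at -0.12 ± 0.12, myf5 at -0.06 ± 0.09 and Pax7 at -0.13 ± 0.28. Those were 0.00 ± 0.10, 0.00 ± 0.07 and -0.33 ± 0.26 without that array. Elovl5b differed by 0.50 ± 0.25 (adjusted p = 0.301) and glucokinase by -1.02 ± 0.38 (adjusted p = 0.150). Glucokinase was well above background on 8 of 8 COM_M, 5 of 8 VEG_M, 1 of 8 COM_V and 4 of 8 VEG_V arrays.

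**Figure D3:**
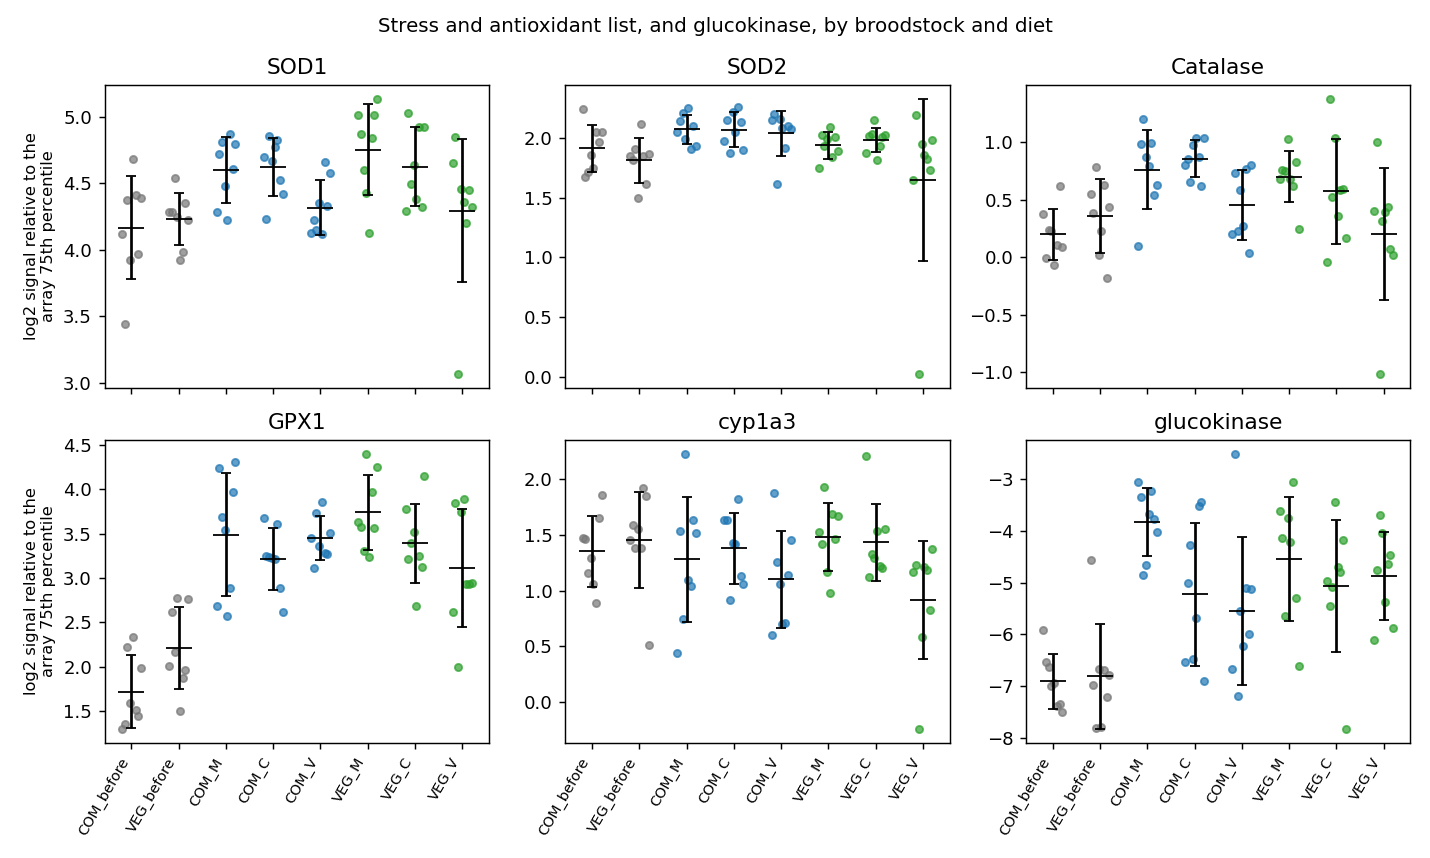
Log2 signal relative to the array 75th percentile (vertical axis) of the 5 genes of the stress and antioxidant list and of glucokinase in the 8 groups (horizontal axis), a point per array with the mean and SD as bars. The lowest VEG_V point of each of the 5 listed genes is replicate 3, and SOD1 on diet V lies below the diet M mean of its broodstock on 14 of 16 arrays.

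Over all probes, 1114 differed between diets V and M, 517 higher and 597 lower on diet V, with median log2 differences of 0.66 and -0.52. The unnamed probe CUST_13022_PI425536763 rose by 3.47 ± 0.40 (11.1-fold, adjusted p = 2.07e-08) and TC117384 fell by 3.56 ± 0.97 on the log2 scale (adjusted p = 0.0309). There were 1214 without VEG_V replicate 3, 657 higher and 557 lower, and 918 of the 1114 were among them. The count was 1683 with slide as a block, 5 within scan day 1 (0 without VEG_V replicate 3, with 3808 at an unadjusted p under 0.05) and 877 within scan day 2, and 0 to 12 within a single slide. Array-median scaling moved the median of all probes by -0.11 and gave 244 higher and 470 lower (448 and 512 without that array). The deposited values gave 683, and a fit of the compared groups alone 374.

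Within the COM broodstock, glucokinase, well above background on 8 of 8 arrays on diet M and 1 of 8 on diet V, did not pass (adjusted p = 0.206). Catalase differed by -0.31 ± 0.17 (adjusted p = 0.900) and SOD1 by -0.28 ± 0.16 (adjusted p = 0.910). Limma called 0 of 57 named probes there (5 unadjusted, 11 without VEG_V replicate 3). Over all probes 197 differed, 162 higher and 35 lower on diet V, of which TC103607 fell by 2.63 ± 0.44 on the log2 scale (adjusted p = 0.000262). The count was 458 without that array (278 higher, 180 lower), which enters through the shared spread, 267 with slide as a block, 0 within scan day 1 (1509 unadjusted, 3131 without that array) and 137 within scan day 2. It was 80 with array-median scaling, 71 with the deposited values and 112 in a fit of the compared groups alone. Within the VEG broodstock, hexokinase, which phosphorylates glucose, rose by 1.07 ± 0.29 (2.10-fold, adjusted p = 0.0395), but by 0.65 ± 0.22 without VEG_V replicate 3, which missed the threshold (adjusted p = 0.191). Adjusted over the list alone, 2 named probes rose and 5 fell in this broodstock, and 0 passed without that array. These were 2 and 7 with slide as a block, and 1 and 1 without that array as well. Adjusted over all probes tested, 2 named probes rose and 2 fell with slide as a block, and 0 passed without that array as well. Over all probes 942 differed there, 581 higher and 361 lower, against 213 (169 higher, 44 lower) without that array, and 163 of the 942 were among these. TC111317 fell by 2.34 ± 0.38 on the log2 scale (adjusted p = 0.000411). The count in the VEG broodstock was 2858 with slide as a block (387 without that array), 106 within scan day 1 (0 without it) and 306 within scan day 2. It was 4 in a fit of the compared groups alone, 290 with normexp and 372 with array weights. Array-median scaling gave 287 higher and 551 lower (79 and 50 without that array), with the median of all probes at -0.21, and quantile scaling 197 and 209, with the median at -0.13.

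The broodstocks rest on separate arrays. Of the 197 probes called in COM, 188 went the same way in VEG (95.4%), and of the 942 called in VEG, 723 went the same way in COM (76.8%). These were, without VEG_V replicate 3, 427 of 458 (93.2%) and 193 of 213 (90.6%). In that setting 93 probes were called in both, all the same way, against 1.16 if the calls were independent. The calls share an estimate of the spread of each probe, so 1.16 may be too low a baseline. The test of whether the diet differences depended on the broodstock called 0 probes with limma (2710 unadjusted), and 0 under each other setting run. Recovery was not simulated for this test. It compares differences, each between groups of 8 arrays, so it is less precise than a single comparison of 8 arrays with 8. Such a comparison, of the broodstocks before feeding, recovered 18% of simulated changes of 0.5 and 68% of changes of 1. A dependence on the broodstock therefore stays open.

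**Figure D4:**
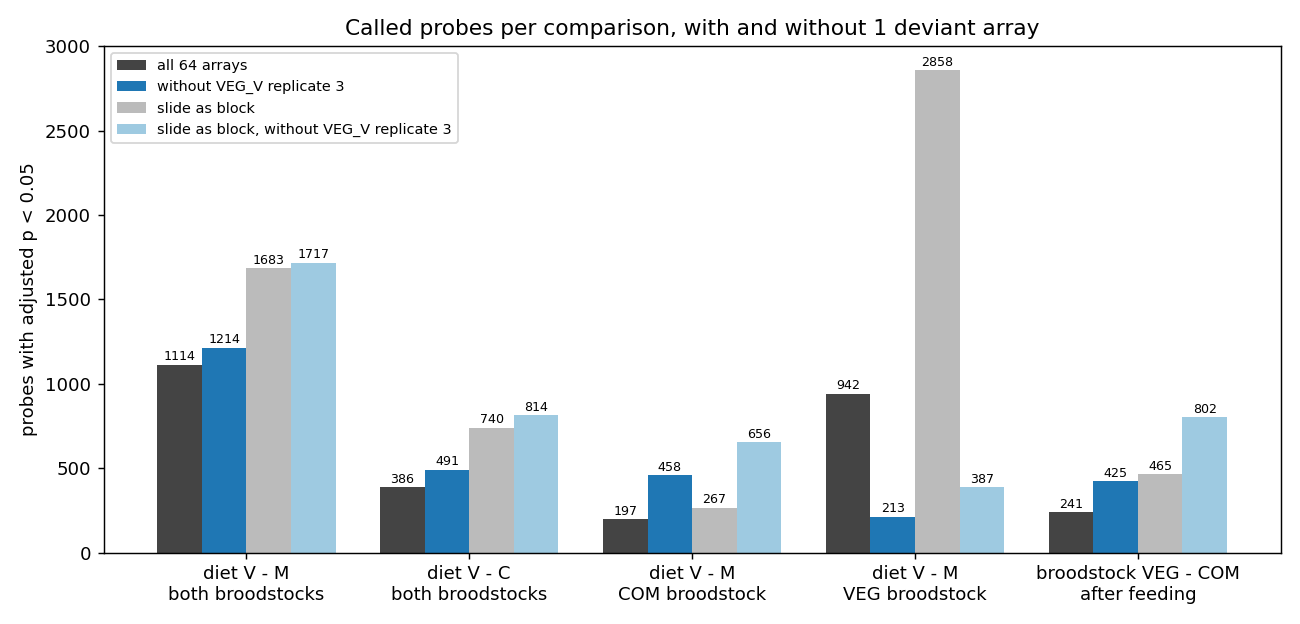
Number of probes with adjusted p under 0.05 (vertical axis, from 0) for 5 comparisons (horizontal axis), as bars for 4 settings. For diet V minus M in the VEG broodstock the bars go from 942 with all arrays to 213 without VEG_V replicate 3, and from 2858 to 387 with slide as a block.

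Diet V was also set against diet C, the mixed feed. The stress and antioxidant list was lower on diet V (mean log2 -0.26, adjusted p = 0.00133), with an adjusted p = 0.0512 with an estimated correlation. Catalase differed by -0.39 ± 0.12 (adjusted p = 0.118), SOD1 by -0.32 ± 0.11 (adjusted p = 0.182) and cyp1a3 by -0.40 ± 0.14 (adjusted p = 0.193), while GPX1 was near 0 at -0.02 ± 0.17 (0.06 ± 0.16 without VEG_V replicate 3). The list mean was -0.17 without VEG_V replicate 3 (adjusted p = 0.00510), and then -0.19 within scan day 1 (adjusted p = 0.00858) and -0.16 within scan day 2 (adjusted p = 0.0311). These p-values, and the next with slide as a block, were computed at the preset correlation alone. With slide as a block its adjusted p was 0.00237, and its mean lay below 0 on 7 of 8 slides (-0.85 to 0.04, the lowest at -0.13 without that array). The myogenesis list did not pass (adjusted p = 0.233). Of the named probes limma called 0 (12 unadjusted, 4 without that array), and over all probes 386 differed, 233 higher and 153 lower on diet V (370 and 121 without that array). TC124030 rose by 2.47 ± 0.33 (5.55-fold, adjusted p = 2.91e-06) and TC126602 fell by 2.22 ± 0.57 on the log2 scale (adjusted p = 0.0395). The count was 740 with slide as a block, 0 within scan day 1 (4199 unadjusted) and 236 within scan day 2, and 0 to 5 within a single slide. It was 145 with array-median scaling, 140 with the deposited values and 36 in a fit of the compared groups alone.

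Diet C and diet M, which both hold fish meal and fish oil, differed in few probes. Limma called 0 of 57 named probes (1 unadjusted, 3 without VEG_V replicate 3). SOD1 differed by -0.05 ± 0.11, Catalase by -0.01 ± 0.12 and GPX1 by -0.31 ± 0.17, and neither the stress and antioxidant list nor the myogenesis list passed (adjusted p = 0.624 for each). Elovl5b differed by 0.45 ± 0.25 and glucokinase, well above background on 4 of 8 COM_C and 2 of 8 VEG_C arrays, by -0.96 ± 0.38, with p of 0.908 and 0.797 adjusted over the list alone. The lipid probes, grouped after the tables had been seen, had a mean of 0.15 (camera adjusted p = 0.0475), with an adjusted p = 0.159 with an estimated correlation and 0.0654 without VEG_V replicate 3. Over all probes 11 differed, 8 higher and 3 lower on diet C, led by TC100902, which rose by 2.27 ± 0.32 (4.82-fold, adjusted p = 3.32e-05), and TC103607, which fell by 1.76 ± 0.31 on the log2 scale (adjusted p = 0.00245). The count was 9 with slide as a block, 0 within scan day 1 (739 unadjusted, 1425 without that array) and 5 within scan day 2, and 0 to 8 within a single slide. It was 7 with array-median scaling, 6 with the deposited values and 20 with array weights.

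Before first feeding, no probe passed the test over all slides between alevins of the 2 broodstocks. For VEG minus COM, limma called 0 of 47172 probes (1367 unadjusted, 2210 without VEG_V replicate 3), 0 with slide as a block, 0 within each scan day and 11 with array weights. Within a single slide, with 1 array per group assumed to vary like the fed arrays, it called 0 to 15. Of the 57 named probes it called 0 (2 unadjusted). GPX1 differed by 0.49 ± 0.23 (SE, 8 arrays per group), Catalase by 0.16 ± 0.17 and SOD1 by 0.06 ± 0.16. Elovl5b was not well above background on any of the 16 arrays. Neither the stress and antioxidant list (adjusted p = 0.184) nor the myogenesis list (adjusted p = 0.376) passed, though the former had an adjusted p of 0.00718 within scan day 1 without VEG_V replicate 3 (mean 0.28) and 0.642 within scan day 2. In simulated values the fit found 68% of changes of 1 on the log2 scale here, so smaller differences remain open.

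After 3 weeks of feeding, over the 3 diets together, limma called 0 of 57 named probes between broodstocks (14 unadjusted). SOD2, the mitochondrial superoxide dismutase, differed by -0.20 ± 0.08 (adjusted p = 0.299), or -0.12 ± 0.05 without VEG_V replicate 3 (adjusted p = 0.237). Catalase differed by -0.20 ± 0.10 (adjusted p = 0.430) and GPX1 by 0.03 ± 0.14 (adjusted p = 0.954), or 0.08 ± 0.13 without that array (adjusted p = 0.863). The muscle factor myod1 differed by -0.21 ± 0.10 (adjusted p = 0.403), or -0.13 ± 0.08 without that array (adjusted p = 0.503). Both lists had an adjusted p of 0.315, the stress and antioxidant list with a mean of -0.06 (0.00 without that array) and a median of 0.02. With slide as a block and without VEG_V replicate 3, GST, chosen after its value was seen, rose by 0.29 ± 0.08 (adjusted p = 0.0413). Adjusted over the list alone 0 passed, but 1 rose and 1 fell without that array, and 3 rose and 5 fell with slide as a block as well (0 with the block and all arrays). TC117158, well above background on 18 of 24 VEG and 6 of 24 COM arrays, rose by 4.65 ± 1.05 (adjusted p = 0.0262). The size of that rise is uncertain, since most COM values lay near background. TC98613 fell by 1.65 ± 0.36 on the log2 scale (adjusted p = 0.0199). Over all probes 241 differed, 60 higher and 181 lower in VEG offspring. There were 425 without VEG_V replicate 3, 158 higher and 267 lower, and 238 of the 241 were among them. The count was 465 with slide as a block, 0 within scan day 1 (2586 unadjusted) and 322 within scan day 2, and 0 to 6 within a single slide. It was 103 with array-median scaling, 98 with the deposited values, 139 in a fit of the compared groups alone and 531 with array weights.

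On single diets, limma called 0 of 57 named probes between broodstocks, and diets M, C and V gave 4, 0 and 16 of them unadjusted (7, 1 and 5 without VEG_V replicate 3). The difference of SOD2 was -0.39 ± 0.14 on diet V (adjusted p = 0.151), but -0.16 ± 0.09 without that array (adjusted p = 0.625). That of GST, chosen after its value was seen, was 0.38 ± 0.18 on diet M (adjusted p = 0.999). Adjusted over the list alone, 3 named probes fell on diet V with slide as a block (Glut2, skelemin and rhbg2a, each at an adjusted p = 0.0221), and 0 without that array as well. Limma called 0 probes on diet M (2308 unadjusted, 3882 without that array), with 2 in a fit of the compared groups alone and 5 within scan day 2. On diet C it called 0 (1153 unadjusted, 2007 without that array), with 1 within scan day 1. On diet V it called TC102371, which fell by 1.33 ± 0.19 on the log2 scale (adjusted p = 0.000186). That count of 1 became 4 without VEG_V replicate 3, 595 with slide as a block (13 without that array), 53 within scan day 1 (0 without it) and 0 within scan day 2. Array-median scaling gave 13 higher and 17 lower (0 and 1 without that array), and the deposited values gave 46.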

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

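The tests on VEG_V replicate 3, those without it, the fits and splits within a scan day and the number of calls in a single diet were chosen after the results were seen.

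VEG_V replicate 3 lay far from the other 7 arrays of its group in median signal (1020.5), spike-in slope (0.891) and mean correlation with other arrays (0.759). It was also the far array for 32 named probes. COM_before replicate 1 was far from its group in median signal (165). Among the other arrays, VEG_C replicate 1 was far for 4 named probes, COM_C replicate 6, COM_V replicate 2, COM_before replicate 2 and VEG_before replicate 1 for 2 each, and the rest of the 22 arrays with any for 1 each. In all, 60 of 445 sets of 8 values passed this rule (13.5%). Those flagged for an array other than VEG_V replicate 3 made up 6.29% of the 445. Chance gives about 1 in 20, but that array stayed in the sets of its group, where it could hide others.

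A fault of hybridisation, amplification or scanning of VEG_V replicate 3 may underlie its values. The spike-in RNA does not come from the fish, and its slope of 0.891 lay outside the range of the other 63 arrays, the lowest of which was 1.01. This argues against a different state of these alevins as the only source. A biological difference in this sample beside a technical one stays open, and which step was at fault was not tested.

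Random splits of the same arrays were counted over the 39684 complete probes, 100 per comparison with the real one. For fed alevins against those before feeding (16459 probes), 1 split, the real one, gave as many, and the highest other gave 4. The same held, with 1 split each, for diet C minus M (10, highest other 1) and V minus C (374, highest other 123). It also held for V minus M in COM (177, highest other 35) and the broodstocks after feeding (237, highest other 53). Chance is thus unlikely for these counts, but the splits exchanged arrays across slides and scan days, so it is not excluded. Splits within a scan day were not run for diet C minus M or for fed alevins against those before feeding. For V minus M in both broodstocks 2 of 100 splits gave as many as the real 1039, and for V minus M in VEG 2 gave as many as the real 821. The highest others were 1361, with 13 of its 16 first-side arrays from scan day 1, and 836. Those shares are small, but the highest other split exceeded the real count in each, so chance is not excluded there either. The split that gave 1361 also held VEG_V replicate 3 on that side, and with arrays exchanged only within a scan day and without that array 1 of 100 reached the real 1154 (highest other 68).

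Chance also stays open for the broodstocks on diet V, where 18 of 100 splits reached the real 2. The highest other split there gave 4082, with 1 of 8 first-side arrays from scan day 1, which points to a structure of the samples. Without VEG_V replicate 3, 8 of 100 reached the real 4 there (highest other 1660), and 7 within scan day (highest other 112). For the counts of 0 the splits decide nothing, since any split gives at least 0 and so all 100 gave as many. These were the broodstocks before feeding (real 0, highest other 2), on diet M (highest other 1), on diet C (highest other 1) and the interaction (highest other 1). With that array left out, 1 of 100 splits reached the real 1154 for V minus M (highest other 52) and 2 reached the real 489 for V minus C (highest other 2998, several times the real count). For V minus M in COM 5 of 100 reached the real 435 (highest other 2037), at the limit, so that the answer depends on the draw and chance stays open in that setting. The splits that gave 2998 and 2037 took 3 of 15 and 1 of 8 first-side arrays from scan day 1. With arrays exchanged only within a scan day, 1 split reached the 489 (highest other 141) and 2 the 435 (highest other 467). For V minus M in VEG, 1 of 100 reached the real 190 (highest other 126), and 2 within scan day (highest other 409). For the broodstocks after feeding 1 reached the real 425 (highest other 2), and 1 within scan day (highest other 409).

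Between the scan days 17753 probes differed among the fed arrays without VEG_V replicate 3, and 628 among the 16 arrays before feeding. Each day held its own 4 slides and its own samples, so scan day, slide and sample set cannot be told apart. Arrays of a slide were taken as independent in that fit, so these counts may be too high. The test of a different effect of diet V minus M on the days called 0 probes with limma (2254 unadjusted).

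Diet V minus M had 877 calls on scan day 2 and 0 on scan day 1 without VEG_V replicate 3. Of the 877 probes, 94.2% went the same way on day 1 (58.1% of all probes did). Their median lay above 0 on 4 of 4 slides, at 0.03 on slide 1 and 0.24 to 0.75 on the others. These values go against a diet difference present only in the samples of day 2, but do not exclude it. No random splits were run for this share, and probes that vary together can reach high shares. For the probes called between broodstocks after feeding, random splits of the arrays before feeding reached 90.5%. Whether a larger spread on day 1 contributes stays open, with a ratio of residual SDs of 1.07 over all groups and 1.03 among the fed arrays, too near 1 to decide. The probes had a median difference of 0.35 on day 1 and 0.64 on day 2, where they had been chosen for passing, so a smaller effect on day 1 and this choice cannot be told apart.

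The broodstocks gave 241 calls after feeding and 0 before. Fewer arrays before feeding may account for this, since a single diet, with the same 8 arrays per side, gave at most 1 call (4 without VEG_V replicate 3, and on diet V with slide as a block 595, or 13 without that array). A difference already present before feeding is also consistent with the data, as 90.9% of the 241 probes went the same way before feeding, against at most 90.5% in the other 99 splits of the 16 arrays. That margin is narrow, and without VEG_V replicate 3 the share was 91.3%, which 2 of 100 splits reached. The parents' diet, their genetic background and tanks stay open as untested sources, and the test of a changed broodstock effect between the time points called 0 probes with limma (828 unadjusted).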

How the results depend on the processing

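The fits without VEG_V replicate 3 and within scan days or slides were added after the data had been seen, and the causes of the moves below were not tested unless stated. The counts of 0 for the interaction stayed 0 under every setting run, and the count for fed alevins against those before feeding stayed within 1.5 times except within scan day 1 (8608) and single slides. Array-median scaling gave 714 probes for V minus M, 7 for C minus M, 145 for V minus C, 80 for V minus M in COM, 103 for the broodstocks after feeding and 30 for them on diet V. The deposited log2 values gave 683, 6, 140, 71, 98 and 46 in the same order. Normexp gave 290 for V minus M in VEG and 4 on diet V, quantile scaling 406 and 7, and no filter 5 on diet V. Array weights gave 11 before feeding, 20 for C minus M, 372 for V minus M in VEG and 531 after feeding. Fits of the compared groups alone, with fewer samples for the spread, gave 374 for V minus M, 36 for V minus C, 112 in COM, 4 in VEG, 139 after feeding, 2 on diet M and 2 on diet V.

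With slide as a block the counts were 1683 for V minus M, 740 for V minus C, 2858 for V minus M in VEG, 465 after feeding and 595 on diet V. With slide as a random block they were 730 for V minus C, 2655 in VEG, 501 after feeding and 515 on diet V. The replicate block gave 605 for V minus C, 1832 in VEG, 390 after feeding and 210 on diet V. Within the fed groups the same number marked the same slide, and deviations from the group means correlated at 0.193 on average over these pairs, with 79.2% above 0.1 and a lowest pair at -0.14. Between fed samples and those before feeding the same number gave -0.00166 and the same slide 0.115. The block changed no other count by more than 1.5 times.

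Without VEG_V replicate 3 the counts were 458 for V minus M in COM, 213 in VEG, 425 after feeding and 4 on diet V. With slide as a block as well they were 1717 for V minus M, 19 for C minus M, 814 for V minus C, 656 in COM, 387 in VEG, 802 after feeding and 13 on diet V, and with array-median scaling as well 317 in COM and 129 in VEG. Within scan day 1 they were 5 for V minus M, 106 in VEG, 53 on diet V and 1 on diet C, with 0 for C minus M, V minus C, COM and after feeding. Without VEG_V replicate 3, day 1 gave 0 for V minus M, C minus M, V minus C, COM, VEG, after feeding and diet V, and 1 on diet C. Day 2 gave 5 for C minus M, 236 for V minus C, 306 in VEG, 5 on diet M and 0 on diet V. Slides 1 to 8 alone gave, in order, 15, 0, 6, 12, 6, 5, 0 and 0 for the broodstocks before feeding, 0, 0, 2, 1, 12, 1, 0 and 9 for V minus M, 1, 0, 5, 4, 8, 0, 0 and 0 for C minus M, 1, 0, 2, 5, 5, 1, 0 and 1 for V minus C, 1, 0, 0, 1, 2, 0, 0 and 6 after feeding, and 45, 1, 296, 394, 954, 3804, 1441 and 859 for fed alevins against those before feeding. On slide 2 without VEG_V replicate 3 these were 1, 0, 0, 0, 2 and 118. Of 3 gene list calls, 1 held with an estimated correlation. A mean over a gene's probes moved nothing, since each tested gene had 1 probe.

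Of the values of the 28 named probes called between fed alevins and those before feeding, 401 kept their direction and side of the threshold, 44 kept their direction and missed the threshold, and 2 turned. With the deposited values myf5 was at 0.017 and the second scleraxis probe at 0.068 on the log2 scale, neither past its test, since the time points were centred separately there. Signal over background limits elovl5b, glucokinase and the probes seen on few arrays.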

Other observations

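Both hypotheses here were written before their tests were run, and the splits without VEG_V replicate 3 were added after the data had been seen.

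If the parents' plant diet and the alevins' own plant diet moved the same genes, probes called for diet V minus M could have gone the same way for VEG minus COM before feeding, on separate arrays. Of the 1114 probes, 54.1% did, with a median difference of 0.02 on the log2 scale, and 20 of 100 random splits of the 16 arrays gave as high a share. The share was 55.6% for the 1214 probes called without VEG_V replicate 3, which 10 of 100 splits reached. No shared shift of these probes was shown. Random splits for the 1114 probes gave shares of up to 62.9%, so the spread of this test leaves such a shift open.

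Diet C, which mixes plant and marine ingredients, could lie between diets M and V. For the 877 probes called on scan day 2 for V minus M, the median C minus M difference on day 1, in the called direction, averaged 0.076 ± 0.079 (SD over 4 slides) and was above 0 on 3 of 4 slides. The V minus M value of the same probes averaged 0.34 ± 0.30, so that C reached 22.1% of it, and the spread between slides left the question open.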
